A study of Homo sapiens with 12 samples.

How the data were processed

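Total RNA from MDA-MB-231 cells was profiled on Illumina single-colour bead arrays, 6 for cells transfected with an LNA gapmer against CYTOR and 6 for a control LNA. Per the labels' protocols, 300000 cells in 2 ml received 30 nM LNA with 5 μl of a lipid transfection reagent and were incubated for 24 h, and the RNA was treated with DNase. Groups, replicate numbers and batches were taken from the labels.

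The deposited table holds log2 values, 1 column per array and 48107 probe rows, of which 784 have no value on any array and were left out. Per the submitters' processing notes the lumi package was used; its version, the transformation (plain log2 or a variance-stabilizing one, which compresses low values) and the normalization method are not given in the sources used here. Values ran from 6.08 to 13.6 and the arrays shared nearly, but not exactly, the same distribution. A batch term fitted beside the group gave p below 0.05 for 1.79% of probes, where 5% is the chance share, a depletion that values already adjusted for batch would show; no source used here states such a step. If so, a fit without the batch term counts degrees of freedom that the adjustment had used. Folds are powers of 2 of differences between deposited values and are understated for dim probes if the transformation compresses them.

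Probes were named through the platform annotation given with the data: 30113 probes had 1 gene symbol, 8 had several and were not named, and 17202 had none there. Older symbols in the gene lists were updated through the RefSeq gene table (assembly GRCh38.p14) and a short table of renamed genes. The RefSeq table also gave gene lengths for 99.9% of tested genes. Probes whose mean over the 12 arrays reached the median of all probes were tested, 23662 probes and 12714 genes. A gene with several tested probes, as 3527 had, was represented by the brightest; 1 called gene had another called probe of opposite sign. No detection p-values were used. Correlations between arrays over tested probes were 0.991 to 0.998, and no pair of arrays held identical values.

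The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) with group and batch as terms on all 12 arrays, which leaves 9 residual degrees of freedom, and Benjamini-Hochberg adjustment over all tested probes at 0.05. Batch was included because the labels record one that is unbalanced over the groups. The target was also tested with an exact permutation of the 12 arrays. The 28 gene lists were tested with camera, with a preset inter-gene correlation of 0.01 and adjustment over the 28 lists, and with an estimated correlation and fry as alternatives. The test, the lists, the alternatives and the naming rule were fixed before the data were examined, and 5 settings for a gene length trend were added afterwards. The naming rule took all CYTOR probes, the 12 largest falls and 12 largest rises among called genes with the same sign in both batches, and up to 4 called members of each list by smallest p; other genes given in the text, further list members included, were chosen after their values were seen.

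The lists covered ErbB receptors and ligands, MAPK output, PI3K and mTOR, actin cytoskeleton, focal adhesion, mesenchymal markers, matrix proteases, YAP and SRF targets, S phase, G2/M, p53 targets, stress responses, chaperones, interferon response, NF-kB targets, sterol synthesis, fatty acid synthesis, hypoxia and glycolysis, respiratory chain, ribosomal proteins, histones, autophagy and lysosome, apoptosis, NRF2 and metallothioneins, CYTOR neighbours, and markers of luminal epithelial cells, fibroblasts and leukocytes. They were written from general knowledge of the pathways, the cell line, the target and LNA gapmer transfection, and not taken from these samples. List members without a named probe were not analysed here.

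The fit was tested on simulated data with the real probe means and spreads for this comparison of 6 against 6 arrays, with probes drawn independently. With 200 of 23662 probes changed by 4 sizes, 64% were recovered at a log2 change of 0.2 and 100% at 0.4, 0.8 and 1.6, and 5.70% of calls were false. With no list shifted, 0 of the 28 lists was called, and with 1 list shifted by 0.15 that list alone was called. Correlated members were not simulated, so this does not check list calls where members vary together.

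Replicate numbers are shared between the groups in the labels, and same-numbered samples can lie in different batches. The numbers were not taken to pair the samples. Alternatives varied the batch term, the replicate block, chip position, the filter on dim probes, the normalization, the variance model, the thresholds and the arrays included.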

Results

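Gene expression was measured in MDA-MB-231 cells, a triple-negative human breast cancer cell line, after transfection with a locked nucleic acid (LNA) gapmer against the long noncoding RNA CYTOR (also named LINC00152) or with a control LNA. Gapmers are antisense oligonucleotides that direct RNase H to cut the RNA they bind. Each group held 6 bead arrays, 1 per sample, and the labels assigned every array to 1 of 2 batches. Batch 1 held 1 CYTOR LNA array and 3 control arrays, and batch 2 held 5 CYTOR LNA arrays and 3 control arrays. Values were deposited for 47323 probes, and the median of each of the 12 arrays was 6.53 on the log2 scale. No bead counts or detection p-values were used here, so the number of arrays limits the precision. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The comparison asks which transcripts change when CYTOR is lowered.

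CYTOR itself was lower in the cells that received its LNA. The brightest of its 3 probes, ILMN_3220934, averaged 6.74 ± 0.10 (SD, n = 6) after the CYTOR LNA and 7.83 ± 0.12 (SD, n = 6) after the control LNA, a 2.15-fold difference (log2 fold change -1.10, SE 0.058). The 6 silenced arrays ranged from 6.64 to 6.86, and the lowest of the 6 controls was 7.72. The exact two-sided permutation test over the 924 splits gave p = 0.0022, the smallest it allows, and limma gave an adjusted p of 8.0e-13. Probe ILMN_3230508 fell by 0.67 on the log2 scale (SE 0.039, adjusted p = 7.0e-12, exact permutation p = 0.0022). Probe ILMN_3230572, the dimmest, had group means of 6.47 and 6.60 and fell by 0.13 (SE 0.034, adjusted p = 0.022 by limma, exact permutation p = 0.0065). The call of this dimmest probe, whose groups overlapped, was lost within batch 2 (limma adjusted p = 0.086), within batch 1 (0.17), without an intensity trend (0.052), and without CYTOR LNA replicate 1 (0.0505) or 2 (0.087) or control replicate 3 (0.075). The level left after silencing, 46.6% of control by the brightest probe, includes any background signal. The silenced means of the other 2 probes, 6.54 and 6.47, lay near the array median of 6.53, where signal was not told apart from background, so their falls may be understated. CYTOR has a near-identical paralogue, MIR4435-2HG, for which the annotation names no probe, so the CYTOR probes may also detect its transcripts.

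**Figure D1:**
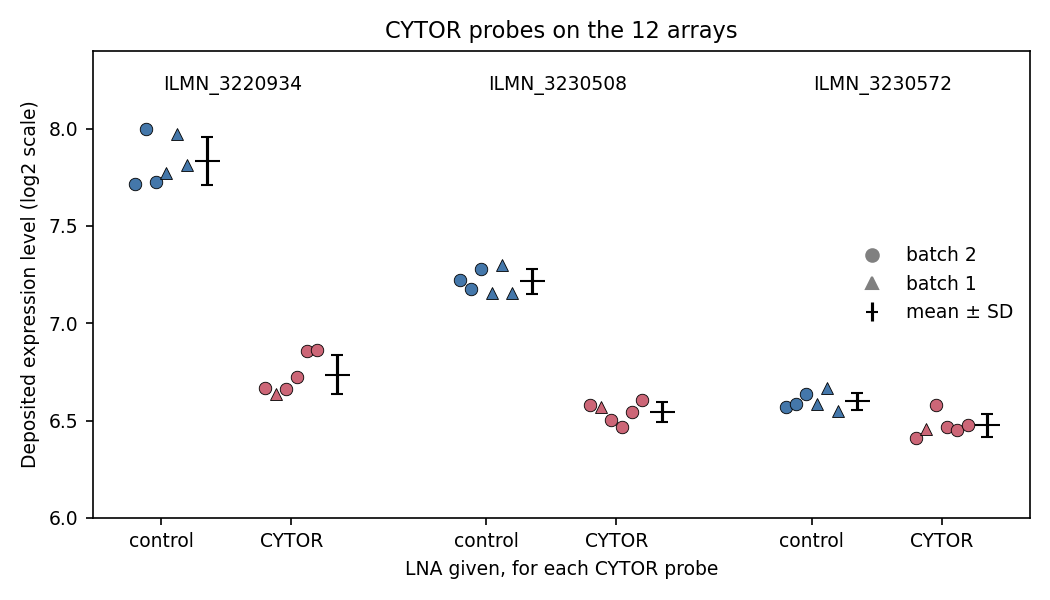
Deposited log2 expression level (y axis) of the 3 CYTOR probes on each of the 12 arrays, by LNA given (x axis). Points are arrays, triangles batch 1 and circles batch 2, and bars show the mean ± SD of 6 arrays. For the brightest probe all 6 silenced arrays, up to 6.86, lie below all 6 controls, from 7.72 upwards.

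Lower expression was the more frequent change. Of 12714 genes tested, 687 fell and 316 rose (limma, Benjamini-Hochberg adjusted p below 0.05), so that 68.5% of the changed genes were lower. Changes were small: the median called fall was 1.19-fold and the median called rise 1.15-fold. At least a 1.5-fold change was seen in 67 of the fallen genes and in 1 of the risen genes, and at least a 2-fold change in 16 and 0. On the level of probes, 973 fell and 502 rose among 23662. The groups did not overlap at all for 682 of the called genes and for 6.76% of all genes tested, where chance gives 0.216%. The fallen genes spanned a median of 83.0 kb of genome, the risen genes 30.4 kb and all tested genes 27.2 kb, by the RefSeq gene table.

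The largest falls reached more than 3-fold. PKP4, a plakophilin of cell junctions, had a mean of 7.28 ± 0.08 (SD, n = 6) after the CYTOR LNA and 9.10 ± 0.04 in controls, which is 3.56-fold lower (log2 fold change -1.83, SE 0.052, adjusted p = 9.4e-18). The RNA-binding protein gene KHDRBS3 was 3.33-fold lower (-1.74, SE 0.056) and GOLPH3, which encodes a Golgi phosphoprotein, 3.28-fold lower (-1.71, SE 0.055). RHOBTB3 was 2.75-fold lower and TMEM115, a Golgi membrane protein gene, 2.57-fold lower. STX8, an endosomal SNARE, was 2.42-fold lower and TTL, the tubulin tyrosine ligase, 2.39-fold lower. HDHD2, PIGU (a subunit of the GPI transamidase), IL1RAPL1, RNLS (renalase) and C8orf76 were between 2.15-fold and 2.24-fold lower. The groups did not overlap for any of these 12 genes. Each of these falls was at least as large as that of the brightest CYTOR probe (-1.10), which background signal may understate. A second PKP4 probe had a log2 fold change of -0.36 and a second KHDRBS3 probe one of -1.12, and the 2 other RNLS probes had log2 fold changes of -0.74 and -0.03.

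The largest rises were smaller. PPHLN1, which encodes periphilin, rose 1.51-fold (log2 fold change 0.60, SE 0.063, adjusted p = 2.6e-07), with 0.23 and 0.71 at its 2 other probes. MAP1LC3A, an LC3 protein of the autophagosome membrane, rose by 0.58 on the log2 scale (SE 0.058). TERF1, a telomere-binding shelterin protein, rose by 0.39 and the nucleolar GTPase gene GNL3L by 0.39, although a second GNL3L probe gave 0.04. VRK3 rose by 0.38 with 0.09 and 0.06 at its other probes, and ITPRIPL2 by 0.37 with 0.08 at its other probe. FNBP1, a membrane-bending F-BAR protein, TSC22D3, a glucocorticoid-induced gene, LGALS3 (galectin-3) and the dynein assembly factor DNAAF5 rose by 0.35 to 0.36. SNAR-A1 (0.41, SE 0.113) and GPR89B (0.41, SE 0.049) have near-identical copies, so their gene assignment is uncertain. SNAR-A1 and ITPRIPL2 had overlapping groups. In batch 1, with its single silenced array, SNAR-A1 differed by 0.74, TERF1 by 0.62, TSC22D3 by 0.62 and LGALS3 by 0.54. Within batch 2 these genes differed by 0.28, 0.30, 0.25 and 0.28. MAP1LC3A, VRK3 and FNBP1 had the larger difference in batch 2.

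**Figure D2:**
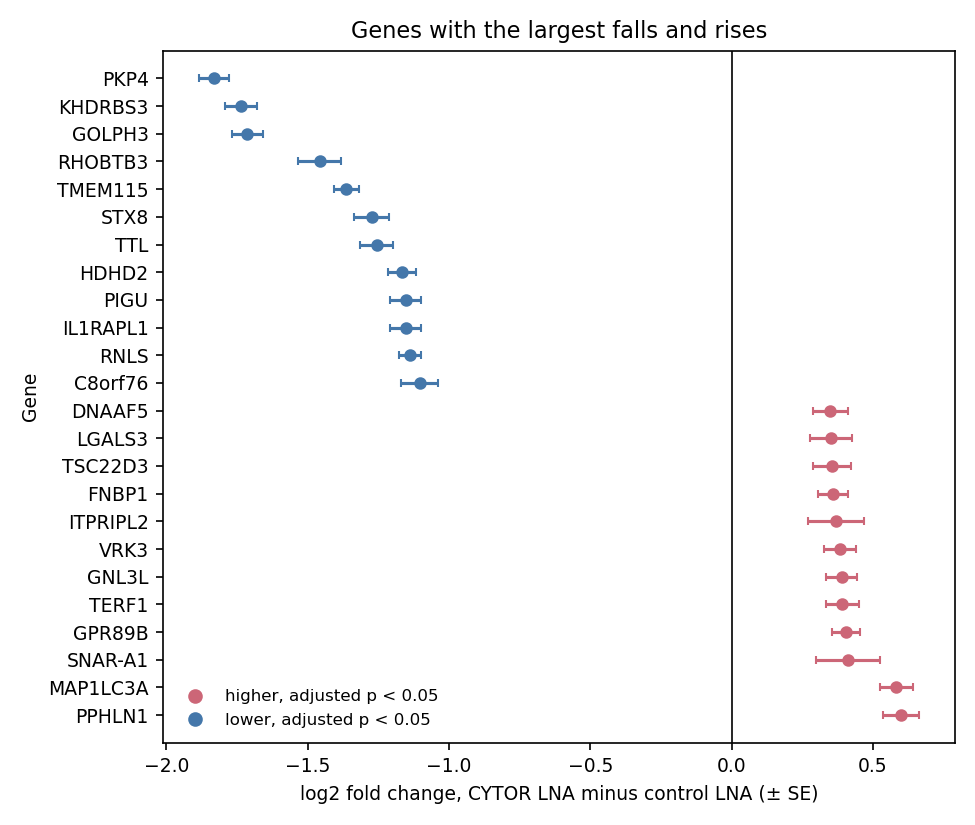
Log2 fold change, CYTOR LNA minus control LNA (x axis), of the 12 genes with the largest falls and the 12 with the largest rises among called genes (y axis). Points are limma estimates from 12 arrays with bars of 1 SE. Falls reach -1.83 at PKP4 and rises 0.60 at PPHLN1.

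Target and feedback genes of the MAPK pathway were among the fallen genes. Of 20 tested, 8 fell, none rose and 12 did not pass; 18 had a negative fold change. PHLDA1 was 1.28-fold lower (-0.35, SE 0.050, adjusted p = 3.1e-05). The feedback inhibitors SPRY1 (-0.35, SE 0.059), SPRED2 (-0.28), SPRY4 (-0.26) and SPRY2 (-0.24) fell, as did IER3 (-0.33), the phosphatase gene DUSP5 (-0.23) and the transcription factor gene MYC (-0.25). A second SPRY4 probe gave -0.05 and a second PHLDA1 probe -0.05. DUSP6 (-0.01), EGR1 (-0.02) and FOS (-0.02) did not pass. Adjusted over the list alone, 10 fell. As a set the list was lower than other genes by camera (adjusted p = 0.00013 with the preset correlation), and this call was lost with an estimated correlation of the members (adjusted p = 0.31 with an estimated correlation) and within batch 1 (0.27), in a range of 3.3e-06 to 0.31 over 28 alternatives. Among 19 ErbB receptors, ligands and signalling partners, 4 fell and none rose: ADAM10, a sheddase of receptor ligands (-0.40, SE 0.049), the EGFR ligand gene TGFA (-0.25, SE 0.058), NRG1 (-0.18) and EGFR itself (-0.18, SE 0.053, adjusted p = 0.040). Second probes of EGFR and NRG1 gave -0.01, and a further NRG1 probe 0.01. Adjusted over the list alone, 6 fell and 2 rose, and as a set the list was not called (camera adjusted p = 0.39). The 4 fallen ErbB list members spanned a median of 177 kb, against 7.24 kb for the 8 fallen MAPK output genes. The lists themselves differed in length, with medians over all tested members of 101 kb for ErbB and 13.5 kb for MAPK output.

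**Figure D3:**
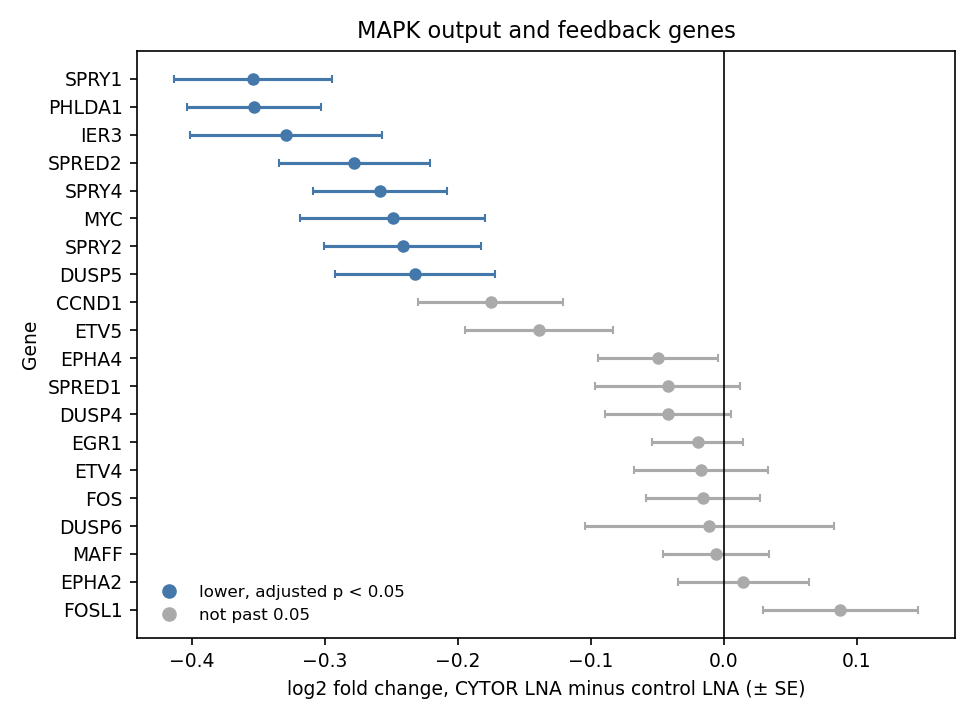
Log2 fold change, CYTOR LNA minus control LNA (x axis), of the 20 tested MAPK output and feedback genes (y axis). Points are limma estimates from 12 arrays with bars of 1 SE, coloured by whether the gene passed an adjusted p of 0.05. The 8 called genes lie at or below -0.23, and 18 of 20 estimates are negative.

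Cell adhesion genes were among the fallen ones. In the focal adhesion list 6 of 27 tested genes fell, 1 rose and 20 did not pass, and adjusted over the list alone the counts were 6 and 1. The adaptor genes PARVA (-0.79, SE 0.054, 1.72-fold), LPP (-0.54, SE 0.066) and LIMS1 (-0.46, SE 0.057) fell, with PTK2, the focal adhesion kinase (-0.37, SE 0.059), TNS3 (-0.23) and TGFB1I1 (-0.21). Talin, TLN1, rose by 0.23. Integrins did not pass, for example ITGB1 at -0.04 (SE 0.059). Second probes gave -0.50 for PARVA, -0.44 for LPP and -0.05 for PTK2, while 3 further LIMS1 probes lay between -0.14 and -0.03. The set was lower by camera (adjusted p = 0.026), and the call was lost without CYTOR LNA replicate 6 (0.11), without control replicate 3 (0.086) and with an estimated correlation (adjusted p = 0.54 with an estimated correlation). It was also lost within batch 1 (0.97), among the brightest 30% of probes (0.052) and with the mean of a gene's probes (0.10), and the lowest value over 28 alternatives was 0.00010. The 6 fallen members spanned a median of 233 kb, against 7.24 kb for the 8 fallen MAPK output genes. Over all tested members the medians were 79.1 kb for focal adhesion and 13.5 kb for MAPK output.

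**Figure D4:**
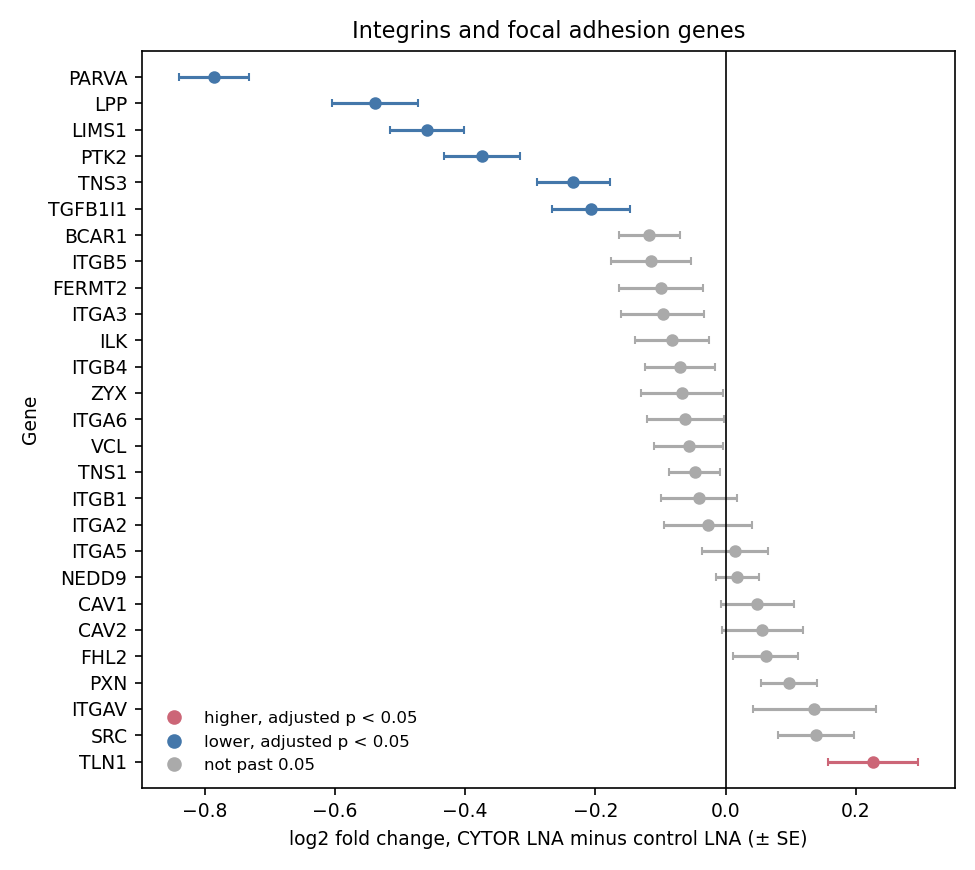
Log2 fold change, CYTOR LNA minus control LNA (x axis), of the 27 tested integrin and focal adhesion genes (y axis). Points are limma estimates from 12 arrays with bars of 1 SE, coloured by whether the gene passed an adjusted p of 0.05. PARVA is lowest at -0.79, and TLN1, at 0.23, is the member called higher.

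Of 48 actin cytoskeleton genes tested, 4 fell and 1 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.84). The formin gene DIAPH2 was 1.87-fold lower (-0.90, SE 0.044), the actin crosslinker ACTN1 1.33-fold (-0.41, SE 0.084), RHOB 1.23-fold (-0.30) and the kinase LIMK2 was lower, with a silenced mean of 6.52 near the array median that leaves the size of its fall uncertain, while WASF2 rose by 0.21. ACTB had a log2 fold change of 0.01 (SE 0.038). In the matrix protease and inhibitor list 3 of 17 fell and 1 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.43). TIMP2, a metalloproteinase inhibitor, was 2.04-fold lower (-1.03, SE 0.061, adjusted p = 9.4e-12), with -0.52 at its second probe. TIMP3 (-0.40, SE 0.065) and the urokinase gene PLAU (-0.27, SE 0.055) fell, and heparanase, HPSE, rose by 0.14, with 0.06 at its second probe. Of 16 mesenchymal markers 2 fell, CD44 (-0.21) and TGFBR2 (-0.21), and none rose (2 adjusted over the list alone; camera adjusted p = 0.91). CD44 had 0.07 and -0.05 at its other probes. VIM had a log2 fold change of -0.02. Of 20 YAP and SRF targets ACTA2 fell (-0.25), and 2 fell adjusted over the list alone (camera adjusted p = 0.91).

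Of 30 G2/M genes NUSAP1 rose (0.19) and BUB1B fell (-0.29), and 21 had a positive fold change (camera adjusted p = 0.089). Of 28 S phase genes PCNA (0.21, with 0.05 at its second probe) and SLBP (0.29), the histone mRNA stem-loop binding protein, rose (camera adjusted p = 0.78). Within batch 2 alone PCNA differed by 0.12 and SLBP by 0.19. For both lists the counts adjusted over the list alone were the same. Of 12 replication-dependent histone genes H2BC5 (0.33, SE 0.064) and H1-2 (0.21, SE 0.062) rose, 3 rose adjusted over the list alone, and 11 had a positive fold change. The set was higher by camera (adjusted p = 0.040), a call lost with an estimated correlation (adjusted p = 0.54 with an estimated correlation) and without CYTOR LNA replicate 3 (0.053) or 6 (0.11) or control replicate 1 (0.090), 2 (0.072), 3 (0.086) or 6 (0.053). The call was also lost among the brightest 30% of probes (0.064), with the mean of a gene's probes (0.062) and by fry (0.067). Over 28 alternatives its adjusted p ran from 0.0016 to 0.98, the latter within batch 1. Histone genes are near-identical copies, so probe signals can be shared. Of 19 p53 targets GDF15 fell (-0.40, SE 0.059) and no other passed, also adjusted over the list alone (camera adjusted p = 0.91). Of 22 apoptosis regulators BCL2L2, which encodes the survival protein BCL-w, fell (-0.53, SE 0.052), while CFLAR (0.18) and CASP9 (0.15, with 0.03 at its second probe) rose, both with overlapping groups (camera adjusted p = 0.73). Adjusted over the list alone 2 of these 22 fell and 2 rose.

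Inflammatory and stress genes showed falls in single members. Of 20 NF-kB targets, cytokines and chemokines 4 fell and none rose, also adjusted over the list alone: NFKB1 (-0.45, SE 0.057), CXCL8, the neutrophil chemokine interleukin-8 (-0.38, SE 0.051), IRAK2 (-0.26) and IL6 (-0.21). A second CXCL8 probe gave -0.10, and the set was not called (camera adjusted p = 0.076). Of 32 interferon-stimulated genes ISG20 (-0.51, SE 0.077), IFIT3 (-0.31, with -0.13 and -0.16 at its other probes) and IFI44 (-0.23) fell while IRF7 (0.24, SE 0.046) and TAP1 (0.20) rose, with the same counts adjusted over the list alone (camera adjusted p = 0.91). Of 24 unfolded protein and integrated stress response genes MANF (-0.22), CEBPB (-0.25) and the chaperone HSPA5 (-0.18) fell, and 4 fell adjusted over the list alone (camera adjusted p = 0.37). By limma no chaperone gene of 15 passed, and 6 were lower at an unadjusted p under 0.05. Adjusted over the list alone 2 fell, HSPD1 (-0.14) and HSPE1 (-0.16), which encode mitochondrial chaperonins (camera adjusted p = 0.19). Of 17 NRF2 targets and metallothioneins MT1E (-0.34), MT2A (-0.26) and HMOX1 (-0.23) fell and NQO1 rose (0.20), with the same counts adjusted over the list alone (camera adjusted p = 0.58). Metallothionein genes are close paralogues.

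In the PI3K and mTOR list MTOR fell (-0.58, SE 0.058, 1.49-fold) and ULK1, the autophagy-initiating kinase, rose (0.28, SE 0.056) among 22 genes tested, and 4 rose adjusted over the list alone (camera adjusted p = 0.58). Of 25 autophagy and lysosome genes ATG7, the E1-like enzyme of autophagy, fell 1.61-fold (-0.69, SE 0.051) and WIPI1 1.29-fold (-0.37), while MAP1LC3A (0.58) and ULK1 rose. Adjusted over the list alone 3 fell and 6 rose, and the set was not called (camera adjusted p = 0.38). Lipid synthesis lists each held 1 marked fall: LSS, the lanosterol synthase, at -0.56 (SE 0.054) but -0.06 at its second probe, among 18 sterol genes (camera adjusted p = 0.37), and ACACA, which encodes acetyl-CoA carboxylase, at -0.66 (SE 0.051) and -0.62 at its second probe, among 13 fatty acid genes. GPAM rose by 0.18 in the latter list (camera adjusted p = 0.91). Of 27 hypoxia and glycolysis genes the hexokinase HK2 (-0.34, SE 0.063) and BNIP3 (-0.17) fell (camera adjusted p = 0.59). Of 30 respiratory chain genes SDHA fell (-0.24; camera adjusted p = 0.72), and of 28 ribosomal protein genes none passed by limma, with 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.91). The counts of these last 5 lists were the same adjusted over the list alone.

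Protein-coding genes listed as near CYTOR or near its paralogue did not pass by limma: 0 of 13 tested, also adjusted over the list alone and at an unadjusted p under 0.05 (camera adjusted p = 0.91). Genes outside this list were not examined as neighbours. Among markers of other cell types, the keratin KRT18 rose (0.21, SE 0.050, with 0.09 at its second probe) of 15 luminal epithelial markers (camera adjusted p = 0.20), CD14 rose (0.33, SE 0.059, with 0.06 at its second probe) of 8 leukocyte markers (camera adjusted p = 0.44), and ACTA2, also on the YAP and SRF list, fell of 6 fibroblast markers (camera adjusted p = 0.40). The counts adjusted over the list alone were the same. Over all 28 lists camera called 3, MAPK output and focal adhesion lower and histones higher, and with an estimated correlation it called 0. The median, mean and camera direction differed in sign for the actin, YAP and SRF, S phase, p53 and apoptosis lists, none of which was called. Groups also overlapped for the called members EGFR, ACTN1, WASF2, CD44, TGFBR2, ACTA2, HSPA5, GPAM, H1-2, NQO1 and HMOX1.

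Within batch 2, which held 5 CYTOR LNA and 3 control arrays, 601 genes fell and 336 rose, of which 516 and 165 were also called over both batches. Within batch 1, with a single CYTOR LNA array assumed to vary like the other arrays, 843 fell and 676 rose, with 391 and 140 shared. All values within batch 1, lost list calls included, rest on that single array and say little about the LNA. Of the 1003 genes called over both batches, 992 had the same sign in each. The call itself used both batches, so this agreement was likely and is no independent check. The share over all tested genes was not computed. Leaving out control replicate 2 lowered the count of risen genes to 198. CYTOR LNA replicate 2 stood apart from the other silenced arrays on the second principal component (15.2 against -1.43 to -6.19), and without it 570 genes fell and 313 rose, of which 501 and 161 were also called over all 12 arrays.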

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

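All values here come from a rule fixed beforehand, and no test was chosen after the result was seen. Each named gene and CYTOR probe was checked, in each group of 6 arrays, for 1 array far from the other 5. Of 174 such sets 6 held one, where chance alone gives about 1 in 20 sets. CYTOR LNA replicate 2, the single silenced array of batch 1, accounted for 3 of them. TSC22D3 had 8.91 there against 8.52 to 8.56 on the other silenced arrays, PTK2 had 10.55 against 10.78 to 10.85, and PCNA had 10.86 against 10.53 to 10.63. SNAR-A1 had 7.27 on CYTOR LNA replicate 6 against 7.80 to 8.11. WIPI1 had 7.29 on CYTOR LNA replicate 1 against 7.44 to 7.48. MT1E had 10.97 on control replicate 5 against 10.71 to 10.78.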

How the results depend on the processing

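All settings here were planned, except that the ratio of called-lower shares between the longest and shortest genes was chosen after the result was seen. Without the batch term 494 genes were higher. With batch as a random block 1041 genes were lower and 712 higher, with 2678 probes, and within batch 1 676 were higher, with 2564 probes. At an adjusted p under 0.01 there were 451, 104 and 779, and with at least a 1.5-fold change 67, 1 and 83. Leaving out 1 array gave 570 to 695 lower, 198 to 362 higher and 1134 to 1579 probes. No called gene was called in the opposite direction under any of these settings. The replicate block gave 594 lower and 245 higher genes (576 and 221 shared) and a length ratio of 5.5, deviations from the group means correlated above 0.1 for 1 of 6 same-numbered pairs, and 1 of 6 CYTOR LNA arrays correlated best with its own number. The CYTOR probes had -1.14 to -1.05, -0.69 to -0.65 and -0.15 to -0.12 with 1 array left out, and the dimmest missed the threshold at -0.12 within batch 2, -0.14 within batch 1 and -0.13 without trend. The number of lists called was 0 within batch 1 and with an estimated correlation, 1 with the replicate block, the brightest 30% of probes and the mean of probes, 5 without a filter and without trend, 9 by fry, and 1 to 3 with 1 array left out, 1 without CYTOR LNA replicate 6 or control replicate 3. MAPK output had adjusted p = 8.2e-06 to 0.0025 with 1 array left out, 0.27 within batch 1 and 0.31 with an estimated correlation. Focal adhesion had 0.00020 to 0.11 with 1 array left out, 0.97 within batch 1, 0.072 with the replicate block, 0.052 among the brightest probes, 0.54 with an estimated correlation and 0.10 with the mean of probes. Histones had 0.0021 to 0.11 with 1 array left out, 0.98, 0.072, 0.064, 0.54 and 0.062 in the same settings, and 0.067 by fry. G2/M had 0.047 without a filter and 0.043 without trend, and NF-kB 0.030 and 0.049. By fry, which does not compare a list with other genes, NF-kB and matrix proteases had 0.0014, G2/M 0.0015, sterol synthesis 0.0016, ErbB and luminal markers 0.014 and chaperones 0.022. The cause of these shifts was not tested. Of 2100 values of 84 named genes over 25 settings, 1918 kept their call, 182 missed the threshold and 0 reversed. Dim probes near the lowest values limit what can be called.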

Other observations

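The tests of unintended cutting, of CYTOR loss and of the length of called list members, and the settings of the length trend, were chosen only after the result was seen, the member test after the matched lists. Some genes of membrane trafficking stood among the larger falls beyond those already described: TRAPPC8, a tethering complex subunit (-0.79, SE 0.053), the retromer subunit VPS26B (-0.75, SE 0.045), the sorting receptor IGF2R (-0.75, SE 0.070) and STXBP3 (-0.71, SE 0.052). Telomere protein genes went both ways, with STN1 (-0.71, SE 0.048) and ACD (-0.60, SE 0.045) lower and TERF1 (0.39) higher, although a second STN1 probe gave -0.07. TIMP4 (-0.61, SE 0.052) was lower, as were TIMP2 and TIMP3, while TIMP1 had a log2 fold change of 0.01 (SE 0.056), and the mitotic kinesin KIF14 (-0.75, SE 0.066) and KIF2A (-0.73, SE 0.054) were lower while KIF15 (0.31) and KIF4A (0.22) were higher. These genes were chosen after their values were seen, and no enrichment was tested.

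Fallen genes were long, a pattern noticed from their names. In the longest quintile of tested genes (85.5 kb and more) 13.3% were called lower, against 2.44% in the shortest quintile, a ratio of 5.44 (95% interval 4.17 to 7.09; Fisher's exact p = 2.3e-50 across genes, which are not independent replicates). For called rises the shares were 2.13% and 1.97% (Fisher's exact p = 0.77). The ratio was 7.84 without CYTOR LNA replicate 2, 7.56 within batch 2, 8.05 with no filter and 4.9 without the batch term. Of 817 genes over 200 kb, 170 were called lower and 8 higher, among them IL1RAPL1 at 1369 kb, DIAPH2 at 920 kb, PTPRG at 736 kb and RNLS at 412 kb.

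Expression level argues little for this trend, because fallen genes were still 3.02 times as long as uncalled genes matched on mean level (95% range 2.72 to 3.42 over 10000 draws), while risen genes were 1.06 times as long (0.89 to 1.26). Genes over 200 kb did lie slightly lower as a whole, with 71.6% negative. Their median log2 change was -0.040 (bootstrap 95% interval -0.049 to -0.034), a small shift over all such genes tested. Genes near background can show little fall and were not set apart in this median. It therefore cannot decide on a general loss among expressed long genes, which stays open. A candidate explanation is that the gapmer cuts unintended pre-mRNAs, since longer introns offer more chance matches, and the ratio of 5.44 is what that needs, although it was known when this was proposed. Loss of CYTOR itself stays open and cannot be told apart from it, because the labels give 1 LNA type against CYTOR and its sequence was not used here. TMEM115, among the largest falls, spans 4.77 kb, so length does not mark every large fall.

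The MAPK output and focal adhesion lists stood differently towards this trend. The 8 called MAPK genes spanned a median of 7.24 kb, against 25.4 to 245 kb (95% range) in random draws of 8 called-lower genes. All 20 tested members had a median of 13.5 kb, so a short list made that outcome likely. Still, the called members were short, and 0% of 10000 lists matched on length and level had a lower median change. The matched lists argue against the members' own length as the source of the lower list median, as far as members vary independently. The random draws add little, because the list itself is short. The 6 called focal adhesion genes spanned a median of 233 kb, within the range of other fallen genes (20.9 to 280 kb), so unintended cutting may also account for them. The focal adhesion list as a whole had a median change of -0.06 against -0.05 to 0.04 in matched lists, and 1.21% of those had a lower one, so for this list the 2 tests point different ways. All 28 lists were matched in this way, and these percentages were not adjusted over the 28. NF-kB targets had 0.02%, sterol synthesis 1.76%, chaperones 2.02% and G2/M 99.25%. Histones, called higher by camera, had 93.22%, and their median change of 0.04 lay within the matched range (-0.04 to 0.05). The ErbB list had 39.59%, also within its range. Random lists treat members as independent, and the MAPK output and focal adhesion calls were lost with an estimated correlation.

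Drawn splits of the arrays other than the labelled one did not reach the count of changed genes. Of 100 splits of the 12 arrays, drawn from 462 and the labelled one included, 1 gave as many as 1003 called genes. The highest other, which exchanged 1 array between the groups, gave 122. These splits cannot exclude a chance difference between cultures, because the labels do not say whether replicates came from separate ones. They also treat the arrays as exchangeable, which values already adjusted for batch may not be.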
